A study of Mus musculus with 13 samples.

How the data were processed

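Poly(A)-selected, strand-specific RNA-seq libraries were made from whole mouse hearts, per the labels' protocols. The deposited table held expected counts per Ensembl gene for 13 libraries, which the authors estimated with RSEM, per the submitters' processing notes and the file name. These notes also named cutadapt, FastQC, DESeq2 and the genome build GRCm38, without versions, and the file name carried Ensembl release 99. The aligner inside RSEM and the strand setting of the counting were not given in the sources used here. The table listed 55471 genes, and 5.8% of all its values were fractional. No other column of the table was present, and each column was matched to its sample by the library name in the labels.

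Gene symbols, coordinates and exonic lengths came from the GENCODE M21 annotation of GRCm38 by gene ID. Of the 55471 IDs, 55144 matched a symbol, 327 had none and 55230 had coordinates. A symbol was shared by more than 1 ID in 106 cases, and such genes carry their ID.

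Libraries were grouped by genotype and treatment as the labels gave them: 5 libraries of WT control, 4 of R502W control and 4 of R502W mavacamten. The labels number the samples of each group and do not state that each library came from a separate mouse, so p-values measure the spread between these libraries. Before averaging, the 22 pairs of libraries within groups were compared by a chi-square test of their counts. The chi-square per degree of freedom ran from 7.31 to 103.3, so no pair agreed within sampling noise and every library was kept.

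Expected counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its defaults (minimum count 10, minimum total 15), which left 15000 genes. Libraries were scaled by TMM factors. A quasi-likelihood model with 1 mean per group was fitted to all 13 libraries, and each of the 3 comparisons was a contrast of that fit. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and adjusted p-values under 0.05 counted as changes. The biological coefficient of variation was 0.232. Levels are given as CPM on TMM-scaled library sizes, as mean ± SD, and log2 fold changes as edgeR's estimate ± SE. The median SE of expressed genes was 0.11, 0.12 and 0.11 in the genotype comparison, the treatment comparison and the comparison of treated R502W with WT.

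The design, the processing alternatives, 23 gene lists and 16 cell type marker lists were fixed before the data were examined. Lists with at least 5 measured members, 37 of the 39, were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists within each comparison. Camera with an estimated correlation and fry were run beside it. Counts of changed members are given over all genes tested and adjusted over the list alone. The genes named were fixed by a rule. They are 12 fixed cardiac genes, the 8 genes with the largest rise and the 8 with the largest fall among changed genes with a mean of at least 1 CPM and no overlap between the groups, and up to 4 changed members of each list with the smallest adjusted p. Where fewer than 5 genes passed, the 5 genes with the smallest p in each direction are named as values. Other genes named, among them further list members, the markers of other tissues, Cdv3 and the genes given per library, were chosen after their values were seen. Some genes that the rule names are not reported here.

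The share of genotype-changed genes with the opposite sign under mavacamten was computed because the treatment comparison reuses the R502W control libraries. It was set beside 50 simulations with no drug effect and beside the 6 splits of those libraries into separate pairs. The genes called in both comparisons with WT were likewise set beside 50 simulations with no change in any group and beside 20 splits of the WT libraries between the comparisons, added after the data were seen. A genotype score per library, from genes called between WT and all 8 R502W libraries, was added after the data were seen.

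The count test, camera, the length correction and the share of opposite signs were tested on simulated data with known changes. The other tests had no such simulation. With treated means set midway between WT and R502W control, 97.9% of simulated genotype calls had the opposite sign. In that simulation edgeR called 42 genes in the treatment comparison. In the genotype design, 22.4% of genes changed 1.5-fold, 74.6% of those changed 2-fold and 90.9% of those changed 4-fold were called, and 3.1% of calls were unchanged genes. In the treatment design these shares were 31.3%, 73.1%, 95.5% and 3.6%. In the comparison of treated R502W with WT they were 31.3%, 65.7%, 87.9% and 5.4%. In the treatment design camera called 3 of 3 moved lists and no list without a moved gene. The simulated genes varied independently, so this does not check camera's calls where genes of a list vary together.

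Alternatives were edgeR's RLE factors, library totals without scaling, DESeq2 1.42.0, limma voom with sample quality weights, no filter, a filter of 1 CPM in 4 libraries, glmTreat against a fold of 1.2, a fit of only the 2 groups compared, the sample number as a block, covariates for atrial markers and Y-linked genes, and leaving out each library in turn. Alternatives added after the data were seen were the removal of each library's trend on exonic length, the removal of 4 libraries with Adipoq above 50 CPM, an adipocyte marker covariate, and the removal of mitochondrially encoded genes with their nuclear copies. Genes named only by a model number, pseudogenes and sex-linked genes were counted but left out of the rule for named genes. In a simulated length trend, 93 unchanged genes were called without the length correction and 6 with it. RSEM divides reads shared by near-identical genes, so values of such families (Myh6 and Myh7, actins, ribosomal proteins, immunoglobulins, Gstm and Amd genes) are less certain.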

Results

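Whole hearts of 3 groups of mice were profiled by bulk RNA-seq. There were 5 libraries of untreated wild-type (WT) mice, 4 of untreated R502W mice and 4 of R502W mice given mavacamten, called WT control, R502W control and R502W mavacamten below. R502W is a change in cardiac myosin-binding protein C, the thick-filament protein encoded by Mybpc3. Mavacamten is a small-molecule inhibitor of cardiac myosin, and the treated mice received 2.5 mg/kg/day through their drinking water over a course of 21 weeks. The design text gave an age of 24 weeks, while the extraction protocol named hearts of 3 and 18 weeks, and the age of each library was not given in the sources used here. Total expected counts per library ran from 15420583 to 18218404 in WT control, from 15350622 to 19361103 in R502W control and from 16001651 to 17520706 in R502W mavacamten. Sex was not in the labels. All 13 libraries expressed Y-linked genes, with Ddx3y between 36.1 and 73.8 CPM, and Xist was at most 0.64 CPM.

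Hearts within a group differed in genes of other tissues. WT control replicate 2 carried 94.0 CPM of Rag1 and 83.8 CPM of Trbc2, genes of developing and mature T cells, against at most 1.63 CPM of either gene in each other library. Adipoq, the fat hormone adiponectin, exceeded 50 CPM in WT control replicates 2 and 3 (99.5 and 99.3 CPM), R502W control replicate 1 (70.7 CPM) and R502W mavacamten replicate 4 (97.8 CPM). Bmp10, an atrial growth factor, was at 8.33 CPM in WT control replicate 3, 1.57 CPM in R502W control replicate 1 and 6.23 CPM in R502W mavacamten replicate 3, against 307 to 672 CPM in the other libraries. R502W mavacamten replicate 4 held 1404 CPM of the interferon-induced GTPase Iigp1 and 91.5 CPM of Cxcl9.

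The genotype comparison asked how hearts of R502W control mice differed from those of WT control mice. R502W hearts carried more transcript of the slow, fetal-type myosin heavy chain Myh7 (10.4-fold) and of skeletal α-actin Acta1 (9.82-fold), both classic markers of a stressed ventricle. Some members of the stress (10 of 16), sarcomere (10 of 30), matrix (14 of 43) and heat shock (7 of 21) lists rose with them. Camera's calls of these 4 lists were lost with an estimated correlation (adjusted p = 0.208, 0.674, 0.686 and 0.43 with an estimated correlation). Some members of the ribosomal protein (15 of 40), fatty acid oxidation (7 of 34) and oxidative stress (8 of 26) lists fell, and of 18 clock genes 4 rose and 12 fell. The calls of these 4 lists were lost too (adjusted p = 0.674, 0.674, 0.319 and 0.319 with an estimated correlation). In all, edgeR called 1294 genes higher and 562 lower among 15000, and 252 of these 1856 changed at least 2-fold. At an unadjusted p under 0.05 there were 4361 genes, against 750 by chance.

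Among the 12 fixed genes, 7 rose in R502W control hearts and none fell. Myh7 (chromosome 14, 54970684 to 54994626, GRCm38) went from 171 ± 38.8 CPM in WT (n = 5) to 1768 ± 181 CPM (n = 4), a log2 fold change of 3.37 ± 0.29 (SE; edgeR adjusted p = 2.9e-05). Acta1 (chromosome 8, 123891769 to 123894751) went from 135 ± 29.2 to 1326 ± 110 CPM, a log2 fold change of 3.30 ± 0.27 (edgeR adjusted p = 2.55e-05). Nppb, which encodes B-type natriuretic peptide (chromosome 4, 147985788 to 147987205), went from 52.7 ± 20.9 to 196 ± 32.2 CPM (1.90 ± 0.28, edgeR adjusted p = 0.00133). Ankrd1, a stretch-responsive repeat protein, went from 964 ± 148 to 1856 ± 193 CPM (0.94 ± 0.18, edgeR adjusted p = 0.00525). Mybpc3 itself (chromosome 2, 91118144 to 91136516) went from 2513 ± 300 to 3898 ± 247 CPM (0.63 ± 0.12, edgeR adjusted p = 0.00462); its RNA level does not check a missense label. The collagen gene Col1a1 went from 129 ± 27.0 to 221 ± 33.1 CPM (0.77 ± 0.16, edgeR adjusted p = 0.00892). For these 6 genes every R502W control library lay above every WT library, and each call was kept with any 1 library left out. Col3a1 was higher by 0.64 ± 0.18 (edgeR adjusted p = 0.0319), a call that ended without WT control replicates 2 or 4, without R502W control replicates 1, 2 or 3, or without R502W mavacamten replicate 2, with values from 0.48 to 0.75 over the left-out runs, and also with the length trend removed (0.415 ± 0.18). The fast myosin Myh6 (0.50 ± 0.16, adjusted p = 0.057) and Nppa, Postn, Atp2a2 and Pln did not pass.

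**Figure D1:**
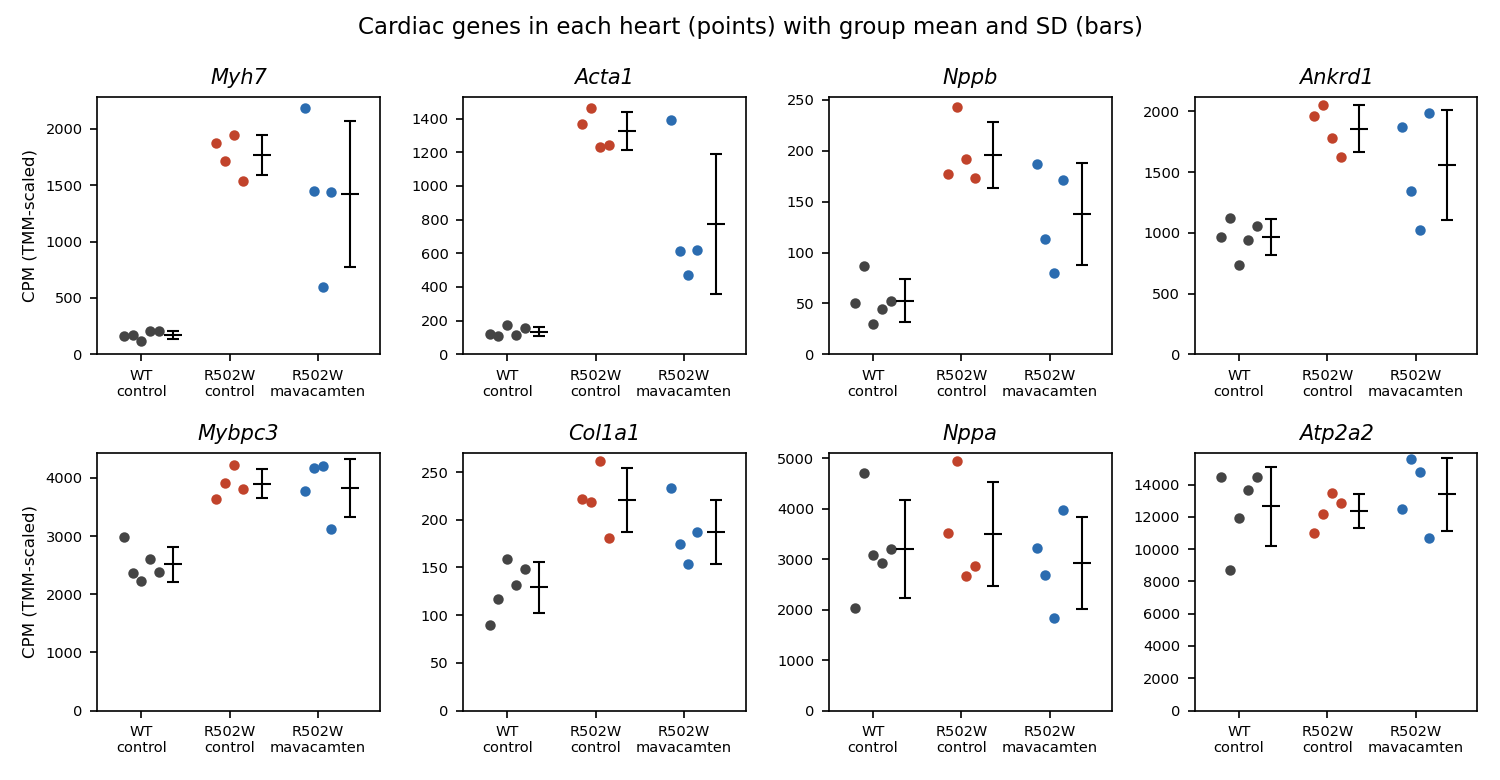
Transcript level of 8 cardiac genes in each of the 13 hearts. The y axis of each panel is TMM-scaled CPM from 0, points are single libraries of the 3 groups on the x axis, and bars are group mean and SD. Myh7 and Acta1 lay at 171 and 135 CPM on average in WT and at 1768 and 1326 CPM in R502W control hearts.

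The largest rises were those of Edn3, an endothelin (3.86 ± 0.36), the growth factor Fgf6 (3.41 ± 0.64), Myh7, Acta1, the aggrecanase Adamts4 (2.95 ± 0.47), the glycosyltransferase Mgat5b (2.92 ± 0.49), Adamts20 (2.66 ± 0.55) and the stress cytokine Gdf15 (2.63 ± 0.43), all kept with any 1 library left out. Among the 8 largest falls, Ciart (-2.88 ± 0.23) and Dbp (-2.18 ± 0.19), both clock-controlled, were also kept in all 13 left-out runs. The other 6 were genes of other tissues or immune cells with a wide spread in WT. Cyp2f2, an airway enzyme, stood at 63.6 ± 92.2 CPM in WT and 0.47 ± 0.27 CPM in R502W control. The calls of Cyp2f2, Pglyrp1, Ighg2c, Cd247, Retnla and Iglc2 ended in 6, 8, 4, 4, 3 and 2 of the 13 left-out runs, and R502W control replicates 2 and 3 were among those libraries for each gene. Over those runs the values ranged from -7.45 to -5.88, -3.81 to -2.83, -3.56 to -2.62, -2.89 to -1.22, -2.57 to -1.998 and -4.20 to -3.40. The value of -1.22 was that of Cd247 without WT control replicate 2. With the length trend removed the calls of Cyp2f2 (-6.93) and Pglyrp1 (-3.33) ended as well.

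The cardiac stress and fetal programme list held 16 measured genes, of which 10 rose and 1 fell, the same numbers adjusted over the list alone (camera adjusted p = 4.92e-08; adjusted p = 0.208 with an estimated correlation). Examples besides those above were Xirp2, a binder of actin at the intercalated disc (1.86 ± 0.15), and Rcan1, a calcineurin regulator (1.52 ± 0.16), while Tnni1, slow troponin I, fell by 1.57. In the sarcomere list 10 of 30 rose and 1 fell, with 15 and 1 adjusted over the list alone (camera adjusted p = 1.1e-05; adjusted p = 0.674 with an estimated correlation). Myot rose by 1.96 ± 0.16 and filamin C (Flnc) by 1.37 ± 0.15, and Tcap fell by 1.14. Of 20 calcium handling genes 4 rose, and 8 rose and 1 fell adjusted over the list alone, without a call for the list (camera adjusted p = 0.104). With the length trend removed only Jph2, which ties the T-tubule to the sarcoplasmic reticulum, remained called (0.49 ± 0.11 before the removal). The calls of Asph (0.44 ± 0.07 before and 0.06 ± 0.08 after), Ryr2 (0.86 ± 0.22 and 0.35 ± 0.12) and Atp2b1 (0.51 ± 0.15 and 0.18 ± 0.08) ended. Ryr2 also lost its call without R502W control replicates 2 or 3 (0.81 and 0.82), and Atp2b1 in 10 of the 13 left-out runs, those 2 included, with values from 0.34 to 0.60 over the 13. No member of the 24 ion channel and gap junction genes passed (camera adjusted p = 0.796). Of 21 adrenergic and natriuretic signalling genes 3 rose, Grk5 by 0.55 ± 0.08, and the angiotensin receptor Agtr1a fell by 0.75, also when adjusted over the list alone (camera adjusted p = 0.302). Among ventricular markers only Mybpc3 of 12 passed (camera adjusted p = 0.824). The 14 atrial markers had no passing member, and the list's call (median -0.24, camera adjusted p = 0.0426; adjusted p = 0.842 with an estimated correlation) held only without WT control replicates 1 or 5 or R502W control replicate 2, with medians from -0.46 to -0.09 over the 13 left-out runs, and ended with the length trend removed (-0.27).

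In the extracellular matrix and fibrosis list 14 of 43 genes rose and none fell, with 17 adjusted over the list alone (camera adjusted p = 1.08e-06; adjusted p = 0.686 with an estimated correlation). Col6a3 rose by 1.01 ± 0.16, Col5a1 by 0.74 ± 0.12, Col8a1 by 1.23 ± 0.21 and the membrane metalloproteinase Mmp14 by 0.69 ± 0.12. Of 14 fibroblast markers 2 rose (camera adjusted p = 0.526) and of 12 mural markers 2 rose, Cspg4 by 0.66 ± 0.12 and Notch3 by 0.56 ± 0.12 (camera adjusted p = 0.796). Of 14 endothelial markers 4 rose, with 7 adjusted over the list alone (median 0.24, camera adjusted p = 0.0266; adjusted p = 0.674 with an estimated correlation), among them the VEGF receptor Kdr (0.73 ± 0.15) and claudin 5, Cldn5 (0.70 ± 0.15); without R502W control replicate 3 the median was 0.21 and the list's call ended. In the angiogenesis and hypoxia list 3 of 20 rose and 1 fell, with 5 and 2 adjusted over the list alone (camera adjusted p = 0.227). Vegfa rose by 0.88 ± 0.12, and Pgf fell by 1.12. With each library's length trend removed, 10 matrix genes and 2 endothelial markers remained called.

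Metabolic transcripts moved down in part. In the fatty acid oxidation list 7 of 34 fell, with 9 lower and 1 higher adjusted over the list alone (camera adjusted p = 1.59e-05; adjusted p = 0.674 with an estimated correlation). Acot1 had a log2 fold change of -0.72 ± 0.14 and the fatty acid transporter Slc27a1 -0.59 ± 0.10. In the nuclear-encoded oxidative phosphorylation list 4 of 48 fell, with 13 adjusted over the list alone (median -0.22, camera adjusted p = 3.01e-09; adjusted p = 0.686 with an estimated correlation). Only 1 of these 4 remained called with the length trend removed, and the list's median was then -0.10. None of the 13 mitochondrially encoded transcripts passed (median -0.03, mean 0.06, camera adjusted p = 0.796), and their levels depend on how reads were divided with nuclear copies. Of 28 glucose use genes 5 rose and 1 fell, with 5 and 2 adjusted over the list alone (camera adjusted p = 0.796). Pfkfb2 rose by 1.10 ± 0.16 and Ppp1r3c, which targets phosphatase to glycogen, by 0.93 ± 0.15, while Pfkfb1 had -1.74 ± 0.29. Of 17 branched-chain amino acid and ketone genes 2 rose and 2 fell, with 2 and 3 adjusted over the list alone (camera adjusted p = 0.796), and the ketone enzyme Bdh1 rose by 1.19 ± 0.22.

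Of 21 heat shock and protein quality control genes 7 rose and none fell, with 9 adjusted over the list alone (camera adjusted p = 0.000175; adjusted p = 0.43 with an estimated correlation). The chaperones Hsph1 and Hsp90aa1 rose by 0.90 ± 0.10 and 0.86 ± 0.13. In the endoplasmic reticulum stress list 3 of 19 rose and 1 fell, with 7 and 1 adjusted over the list alone (camera adjusted p = 0.00374; adjusted p = 0.559 with an estimated correlation). Hyou1 rose by 0.75 ± 0.08 and its regulator Atf6 by 0.89 ± 0.13, while Herpud1 fell by 0.48. Of 20 integrated stress response genes 5 rose, Mthfd2 by 1.63 ± 0.29, and 1 fell, likewise adjusted over the list alone (camera adjusted p = 0.227). Of 26 oxidative stress response genes 8 fell and 1 rose, with 9 and 1 adjusted over the list alone (camera adjusted p = 7.69e-05; adjusted p = 0.319 with an estimated correlation). Glutathione transferase Gstm1 had -0.55 ± 0.08, metallothionein Mt1 -0.60 ± 0.11 and the superoxide dismutase Sod1 -0.45 ± 0.08. The list's median of -0.22 was -0.36 without WT control replicate 1, with the call kept. In the autophagy, lysosome and atrogene list 1 of 22 rose and 2 fell, likewise adjusted over the list alone (camera adjusted p = 0.796). Of 21 immediate early genes 3 rose and 1 fell, with 5 and 1 adjusted over the list alone (camera adjusted p = 0.0266; adjusted p = 0.796 with an estimated correlation). The immediate early list's call ended without WT control replicates 3 or 5 (medians 0.49 and 0.47) and without R502W control replicates 1 or 4 (medians 0.42 and 0.45).

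Of 40 cytosolic ribosomal protein genes 15 fell and none rose, with 27 adjusted over the list alone (median -0.33, camera adjusted p = 4.3e-13; adjusted p = 0.674 with an estimated correlation). Rps6 had -0.62 ± 0.13, and 11 of the 15 remained called with the length trend removed. The ribosomal proteins stood highest in WT control replicate 2, the library with the T cell genes, and without it the list's median was -0.24 with its call kept. The circadian clock list changed in 16 of 18 genes, 4 higher and 12 lower, also adjusted over the list alone (camera adjusted p = 8.78e-05; adjusted p = 0.319 with an estimated correlation). Arntl, the activator of the core loop, rose by 2.43 ± 0.28 and its partner Npas2 by 1.69 ± 0.23, while the repressors Per2 and Per3 had -1.65 ± 0.19 and -1.15 ± 0.15. All 16 remained called with the length trend removed. The time of day at collection was not given in the sources used here.

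**Figure D2:**
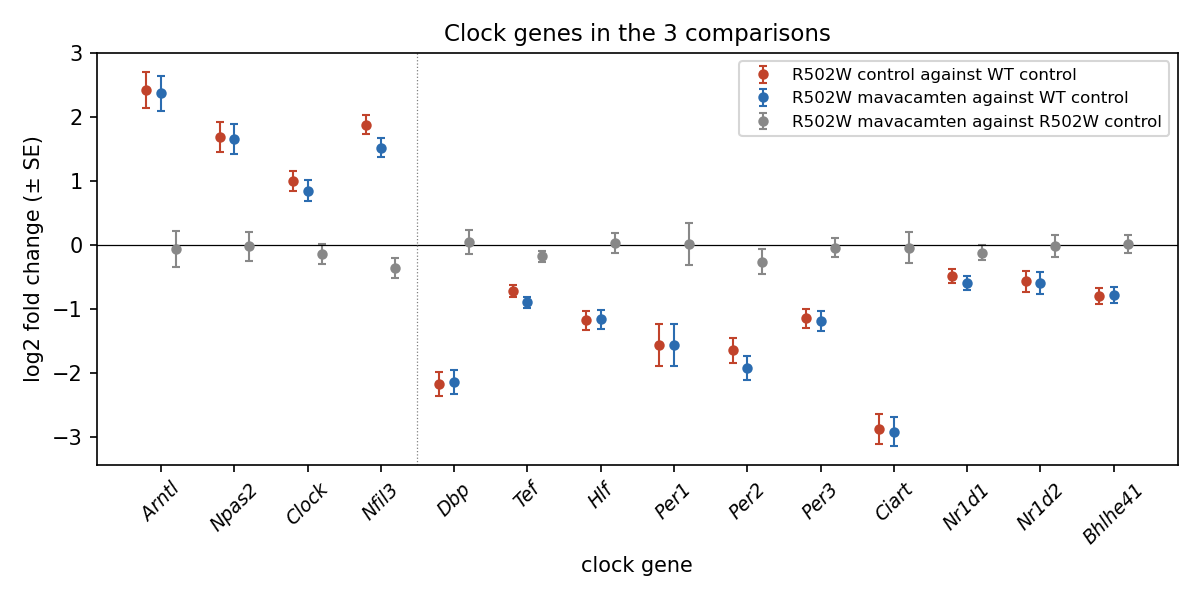
Log2 fold change (y axis) of 14 clock genes (x axis) in the 3 comparisons, with bars of 1 SE. The 4 genes left of the dotted line cycle with Arntl and the 10 others in the opposite phase. R502W control and R502W mavacamten hearts stood apart from WT alike, with Arntl at 2.43 and 2.37 and Ciart at -2.88 and -2.92.

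Immune and remaining marker lists moved little or through few libraries. In the interferon list 1 of 30 rose (Rsad2), in the inflammation list 1 of 24 rose (Tnfrsf12a, the TWEAK receptor, 1.90 ± 0.20) and 1 fell (Il33), each also adjusted over the list alone, and no cell cycle gene of 22 passed (camera adjusted p = 0.796, 0.927 and 0.0612). Rsad2 and Il33 lost their calls without R502W control replicate 3, with 1.10 and -0.93. The lymphocyte markers stood lower, 1 of 11 over all genes and all 11 adjusted over the list alone (median -2.16, camera adjusted p = 0.00684; adjusted p = 0.757 with an estimated correlation), and without WT control replicate 2 the call ended at a median of -1.13. The 9 mesothelial and epicardial markers had no passing member (median -0.88, camera adjusted p = 0.00842; adjusted p = 0.686 with an estimated correlation), and the list's call ended without WT control replicate 2 (-0.71) and without R502W control replicate 3 (-0.66). Among 8 Schwann cell and nerve markers Sox10 fell, also adjusted over the list alone (median -0.47, camera adjusted p = 0.0225; adjusted p = 0.559 with an estimated correlation); the list's call ended without WT control replicates 2 or 3 (-0.42 and -0.41) and without R502W control replicate 3 (-0.54). Sox10 (-1.21 ± 0.31) lost its own call without R502W control replicates 1, 2 or 3, with values from -1.37 to -1.09 over the left-out runs. Camera called none of the macrophage (1 of 15 rose), neutrophil (5 measured), erythroid (6), adipocyte (9), skeletal muscle (6) and valve and cartilage (1 of 6 rose) lists, with adjusted p-values from 0.197 to 0.927. The single measured lung gene, Scgb1a1, stood at 120 ± 166 CPM in WT and 0.31 ± 0.31 CPM in R502W control. No thymus marker passed the count filter, which asks for counts in several libraries, so this does not show their absence. The thymus marker Rag1 stood at 94.0 CPM in WT control replicate 2 and at most 1.63 CPM in each other library. Median, mean and test differed in sign in the mitochondrially encoded, autophagy, branched-chain amino acid, inflammation, ventricular, mural and valve lists, none of them called.

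Fold changes in the genotype comparison rose with exonic length, with a rank correlation of 0.34 across 14990 genes, which are not independent replicates, and 1064 of the 1856 calls remained in the same direction when each library's length trend was removed. The count fell to 866 without R502W control replicate 2, 914 without replicate 3 and 1040 without replicate 1 of that group. The share of calls that were higher was 69.7% in edgeR, against 56.2% in DESeq2 (1386 higher and 1081 lower). Within edgeR it was 60.3% with RLE factors, 59.8% with the length trend removed and 76.9% with library totals. Over the left-out runs it ran from 58.8% (without R502W mavacamten replicate 3) to 77.8% (without R502W control replicate 1).

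**Figure D3:**
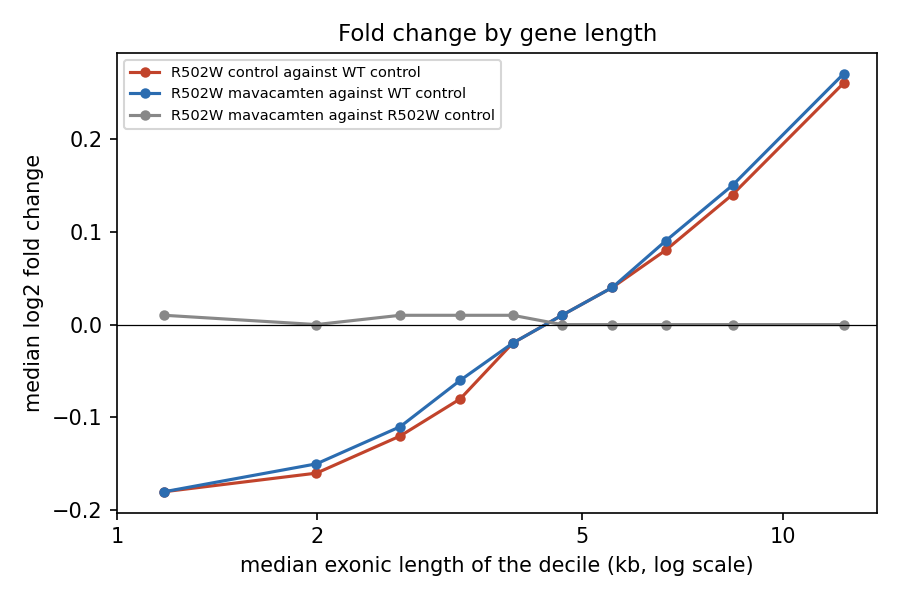
Median log2 fold change (y axis) against the median exonic length (x axis, kb, log scale) of 10 equal groups of genes ordered by length. Lines join the groups of 1499 genes in each comparison. Both comparisons of R502W hearts with WT rise from -0.18 to 0.26 and 0.27, while the treatment comparison stays between 0.00 and 0.01.

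The treatment comparison asked what mavacamten changed in R502W hearts. No gene passed edgeR's threshold, and the values that follow are given without a claim of change. Acta1 stood at 1326 ± 110 CPM in R502W control and 773 ± 417 CPM in treated hearts (log2 fold change -0.78 ± 0.27), with 1390 CPM in replicate 1 and 471 to 621 CPM in the other 3. Myh7 stood at 1418 ± 647 CPM under the drug (-0.32 ± 0.29), Nppb at 138 ± 50.04 CPM (-0.51 ± 0.29) and Mybpc3 at 3823 ± 503 CPM (-0.03 ± 0.12). The edgeR count of 0 compares with 525 genes at an unadjusted p under 0.05, where 750 were due by chance, 6 genes by DESeq2, Cpxm2, Amd2, Ptgds, Gstm1 and Cdv3 among them, and 2 by limma voom, Ptgds among them.

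The carboxypeptidase-like gene Cpxm2 had -0.83 ± 0.14 (edgeR adjusted p = 0.408) and Ptgds, a prostaglandin D synthase, -0.96 ± 0.19 (edgeR adjusted p = 0.957). Pald1 had -0.37 ± 0.08 and Amd2 -5.96 ± 1.297. Untreated R502W libraries were split in Amd2, at 0.52, 0.39, 17.3 and 17.5 CPM, against at most 0.23 CPM in treated hearts, so its fold and its DESeq2 call rest on 2 libraries. The 5 highest by p were Fam163b (1.82 ± 0.43), Gstm1 (0.36 ± 0.08), Nqo1, a quinone reductase (0.52 ± 0.13), Lgals4 (0.60 ± 0.15) and Kcna6 (1.07 ± 0.27), each at an edgeR adjusted p of 1. The remaining fixed genes lay between -0.47 for Postn and 0.18 for Pln.

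No list held a member that passed over all genes. Camera called 16 of 37 lists at the preset correlation and 0 with an estimated one, and fry called 0. The cardiac stress list stood lower (median -0.26, camera adjusted p = 9.73e-08; adjusted p = 0.22 with an estimated correlation), with 5 of 16 members lower adjusted over the list alone, namely Gdf15 (-1.57), Acta1, Nmrk2 (-0.77), Rcan1 (-0.66) and Xirp2 (-0.64). Extracellular matrix genes stood lower (median -0.19, 37 of 43 negative, camera adjusted p = 5.91e-10; adjusted p = 0.377 with an estimated correlation), as did fibroblast markers (-0.16, 0.000139; adjusted p = 0.377 with an estimated correlation) and endothelial markers (-0.14, 0.000948; adjusted p = 0.316 with an estimated correlation). The integrated stress response list stood at -0.18 (camera adjusted p = 3.1e-06; adjusted p = 0.22 with an estimated correlation), with Mthfd2 (-1.14) and Gdf15 lower adjusted over the list alone. The heat shock list stood at -0.10 (camera adjusted p = 1.31e-05; adjusted p = 0.239 with an estimated correlation), with Hsph1 (-0.47) lower adjusted over the list alone, and the endoplasmic reticulum stress list at -0.13 (9.67e-06; adjusted p = 0.234 with an estimated correlation). Immediate early genes stood at -0.29 (2.66e-05; adjusted p = 0.377 with an estimated correlation) and erythroid markers at -0.34 (2.57e-05; adjusted p = 0.316 with an estimated correlation). These calls were kept with any 1 library left out, while several medians shifted. Without R502W mavacamten replicate 3 the cardiac stress, matrix, immediate early and erythroid medians were -0.10, -0.11, -0.17 and -0.22. Without replicate 1 of that group the matrix and immediate early medians were -0.32 and -0.50, and without its replicate 2 the immediate early and integrated stress medians were -0.15 and -0.095. The endothelial median was -0.09 without R502W mavacamten replicate 4, and the heat shock median -0.07 without R502W control replicate 4.

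Lists that stood higher under the drug included fatty acid oxidation, with 33 of 34 genes positive at a median of 0.11 (camera adjusted p = 1.98e-06; adjusted p = 0.377 with an estimated correlation). That median was 0.07 without R502W control replicate 2 or R502W mavacamten replicate 3, with the call kept. The oxidative stress list stood at 0.08 (camera adjusted p = 0.000451; adjusted p = 0.316 with an estimated correlation), with Gstm1 and Nqo1 higher adjusted over the list alone. Oxidative phosphorylation (0.06, 0.00859; adjusted p = 0.839 with an estimated correlation) and branched-chain amino acid and ketone use (0.08, 0.0232; adjusted p = 0.653 with an estimated correlation) lost their calls without R502W control replicates 1 or 2 and without R502W mavacamten replicates 2 or 3, with medians from 0.02 to 0.11 and 0.04 to 0.14 over the left-out runs. The interferon list stood at 1.01 with all 30 genes positive and 8 higher adjusted over the list alone (camera adjusted p = 4.36e-09; adjusted p = 0.434 with an estimated correlation), and at -0.02 without R502W mavacamten replicate 4. Lymphocyte markers (0.82, 0.0232; adjusted p = 0.683 with an estimated correlation) and Schwann cell markers (0.46, 0.00992; adjusted p = 0.316 with an estimated correlation) lost their calls without that library (0.35 and 0.38) or R502W mavacamten replicate 1 (0.69 and 0.16), the latter list also without R502W control replicate 3 (0.37). The clock list stood at -0.05 (camera adjusted p = 0.053), and the other 20 tested lists were not called either, the sarcomere list at -0.03 and ribosomal proteins at -0.03 among them. The adipocyte list's median was 0.38 while its test pointed down (camera adjusted p = 0.729), and median, mean and test also differed in sign in the glucose use, inflammation and mural lists.

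**Figure D4:**
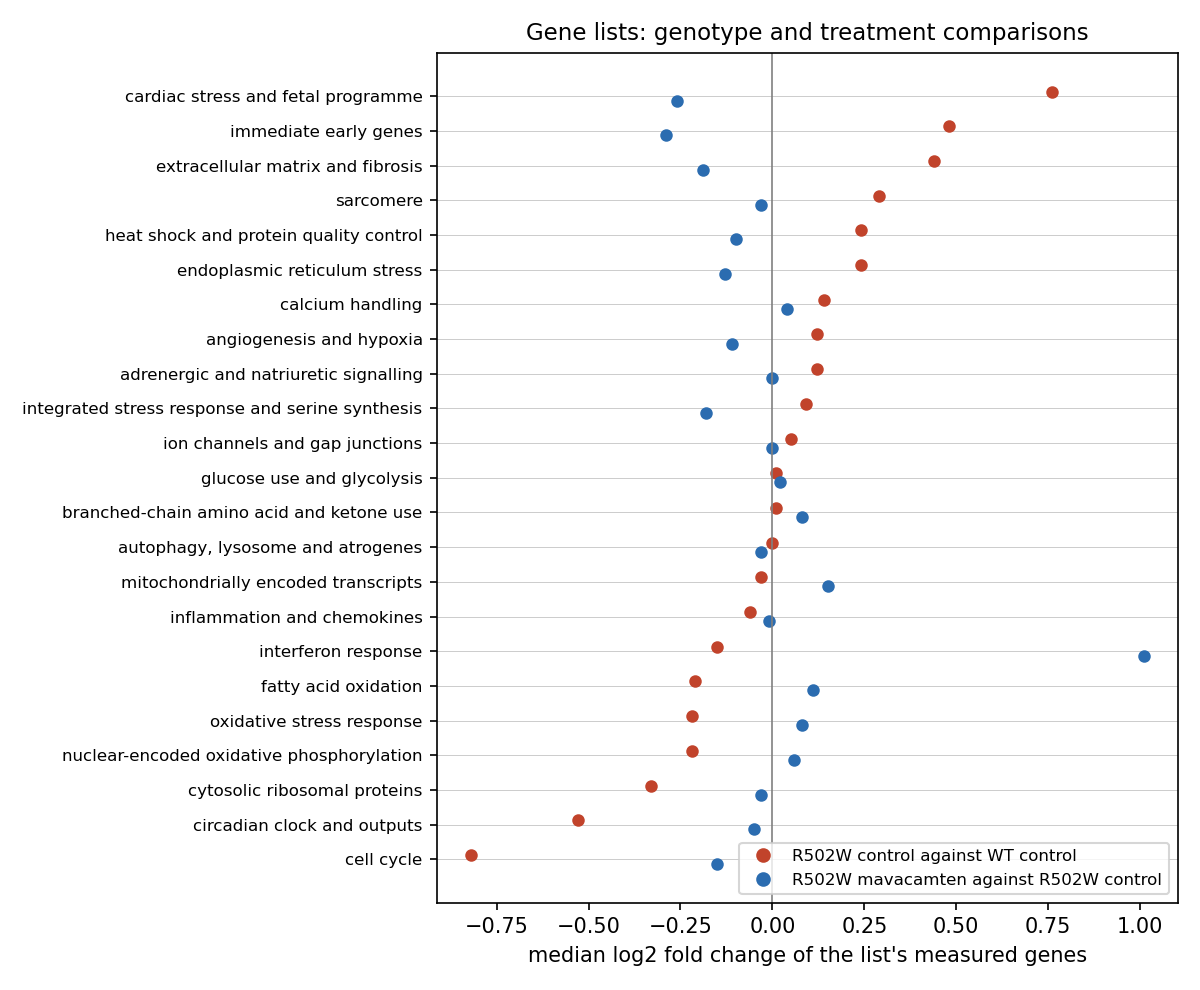
Median log2 fold change (x axis) of the measured genes of each of the 23 gene lists (y axis) in the genotype comparison (red) and the treatment comparison (blue). The cardiac stress list lay at 0.76 and -0.26, the matrix list at 0.44 and -0.19, and the fatty acid list at -0.21 and 0.11.

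Of the 1856 genotype-changed genes 1493, or 80.4%, had the opposite sign under mavacamten. Because both comparisons used the R502W control libraries, simulations with no drug effect also gave 67% (64.7 to 69.1 over 50 simulations), and with those libraries split between the comparisons the share averaged 76.4% (68.0 to 85.6 over 6 splits). The simulations called 2382 genotype genes on average (2253 to 2512), more than the observed 1856. They took the observed group means as true means, so noise in those means counted as genotype change. The simulated share and slope may therefore be too low as a reference. The simulations also drew genes independently, so their ranges leave out shifts that genes of a library share. The covariance of the 2 fold changes was -0.129 against -0.0599 simulated, a difference of -0.0691, and averaged -0.1011 with split libraries (-0.1129 to -0.0893). Their correlation across genes was -0.55 against -0.26 simulated (-0.325 to -0.19), and averaged -0.33 with split libraries (-0.37 to -0.28). Over the genotype-changed genes the slope of the mavacamten fold change on the genotype fold change, with its sign reversed, was 35.2%, against 11.3% simulated (6.0 to 16.6) and 13.3% with split libraries (8.0 to 23.2). The simulated values keep the libraries shared, so they are no reference for the values with split libraries. On a genotype score that set mean WT at 0 and the mean of all R502W hearts at 100, R502W control hearts stood at 105.3 ± 8.3% (SD, n = 4) and treated hearts at 94.7 ± 7.6% (n = 4). The difference of -10.6 points had a two-sided exact permutation p of 0.114 over 70 assignments, of which the smallest possible is 0.0286. With the length trend removed it was -13.3 points (permutation p = 0.0571). Leaving out 1 R502W library gave -14.6 to -7.2 points (permutation p from 0.0571 to 0.371). The score's genes were called over all R502W libraries together, which disfavours genes that the drug returned to WT.

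**Figure D5:**
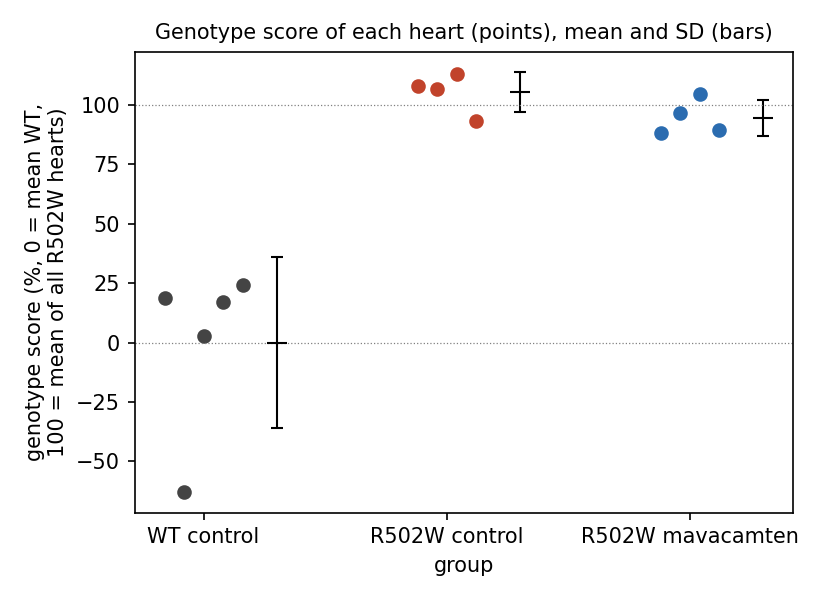
Genotype score of each heart (y axis, percent, 0 for mean WT and 100 for the mean of all R502W hearts) by group (x axis). Points are libraries and bars are mean and SD. WT control replicate 2 lies at -62.7, the other WT hearts between 2.7 and 24.3, R502W control hearts between 93.4 and 112.9, and treated hearts between 88.1 and 104.5.

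The last comparison asked how far treated R502W hearts stood from untreated WT; no treated WT group was analysed here, so drug and genotype are not crossed. Treated hearts still carried more Myh7 (3.06 ± 0.29, edgeR adjusted p = 0.000173), Acta1 (2.52 ± 0.27, edgeR adjusted p = 0.000297), Nppb (1.39 ± 0.28, edgeR adjusted p = 0.0121) and Mybpc3 (0.61 ± 0.12, edgeR adjusted p = 0.0111) than WT hearts. Clock genes stood as far from WT as in R502W control hearts, with Arntl at 2.37 ± 0.28. Col1a1 (0.54 ± 0.16, adjusted p = 0.0586) and Col3a1 (0.49 ± 0.18, adjusted p = 0.103) no longer passed, a difference between comparisons that was tested only through the treatment contrast. edgeR called 889 genes higher and 343 lower, 159 of them at least 2-fold, with 3877 at an unadjusted p under 0.05.

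Of these 1232 genes 997 were also called with the same sign in the genotype comparison and none with the opposite sign, 760 higher and 237 lower, where independent lists would share 76.7 and 12.9. Both comparisons used the WT libraries, which can raise this overlap. The fold changes of the 2 comparisons correlated at 0.745, and at 0.442 on average in 50 simulations with no change in any group (0.416 to 0.489). Genes were drawn independently there too, so this range leaves out shifts that genes of a library share. With the WT libraries split between the comparisons in 20 ways, an average of 124.2 higher and 34 lower genes were shared (13 to 370 and 8 to 87), against 13.6 and 2.7 for independent lists, with at most 1 of opposite sign, and the correlation averaged 0.368 (-0.017 to 0.49). The largest rises were Edn3 (3.41 ± 0.36), Cd274, Myh7, Gbp7, Acta1, Arntl, Ifi213 (2.22 ± 0.50) and Adamts4 (2.16 ± 0.48), and the largest falls included Amd2 (-6.62 ± 1.27), Ciart (-2.92 ± 0.23), Dbp (-2.14 ± 0.19), Per2 (-1.92 ± 0.19), Mthfd1l, Per1 and Stra6. The interferon-induced Cd274 and Gbp7 stood at 3.24 and 2.64, and without R502W mavacamten replicate 4 at 0.24 and 0.58 with no call; their calls ended in 10 and 7 of the left-out runs, that one included. Ifi213, also interferon-induced, stood at 1.12 without that library and kept its call. Adamts4 lost its call without R502W mavacamten replicate 2 (1.85), as did Per1 (-1.44). Mthfd1l and Stra6 lost theirs in 2 and 6 of the 13 left-out runs, R502W mavacamten replicates 2 and 3 among them. Ankrd1 (0.69 ± 0.18, edgeR adjusted p = 0.0328) and Myh6 (0.57 ± 0.16, edgeR adjusted p = 0.0447) passed, and lost their calls in 7 and 11 of those runs, with values from 0.52 to 0.84 and from 0.46 to 0.62. With the length trend removed the calls of Myh6 (0.46 ± 0.15), Cd274 (3.29 ± 0.89) and Gbp7 (2.59 ± 0.69) ended. Postn, Nppa, Atp2a2 and Pln did not pass.

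In the cardiac stress list 8 of 16 rose, with 8 higher and 1 lower adjusted over the list alone (camera adjusted p = 5.22e-05; adjusted p = 0.428 with an estimated correlation), and Xirp2 rose by 1.22 ± 0.15. In the sarcomere list 11 of 30 rose and 1 fell, with 14 and 1 adjusted over the list alone (1.95e-05; adjusted p = 0.816 with an estimated correlation). Of 40 ribosomal protein genes 15 fell, with 29 adjusted over the list alone (camera adjusted p = 9.63e-17; adjusted p = 0.816 with an estimated correlation). The clock list again held 4 higher and 12 lower genes, also adjusted over the list alone (3.33e-06; adjusted p = 0.315 with an estimated correlation). Of 48 oxidative phosphorylation genes 3 fell, none of them adjusted over the list alone (9.2e-07; adjusted p = 0.816 with an estimated correlation), and with the length trend removed none remained called and the list's call ended at a median of -0.05. Of 26 oxidative stress genes 2 rose and 6 fell, with 4 and 8 adjusted over the list alone (0.0178; adjusted p = 0.816 with an estimated correlation), a call that ended with the length trend removed (median -0.19 before and -0.10 after). The oxidative stress median was -0.11, -0.09 and -0.11 without WT control replicates 3 or 5 or R502W mavacamten replicate 3, and the oxidative phosphorylation median of -0.16 was -0.25 without the last of these, with both calls kept. Nqo1 rose by 0.57 ± 0.12 over WT, without a call once R502W mavacamten replicate 2 was left out (0.46), and Hmox1, heme oxygenase, had -0.71 ± 0.14. Mesothelial markers stood at -0.96 (camera adjusted p = 0.00115, 1 of 9 lower, 3 adjusted over the list alone) and atrial markers at -0.42 (0.00472, no member passing), each with an adjusted p of 0.816 with an estimated correlation.

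The matrix list (5 of 43 higher, 8 adjusted over the list alone, camera adjusted p = 0.0424) lost its call without WT control replicates 1, 2 or 4 or R502W mavacamten replicates 1 or 4, with medians from 0.07 to 0.29. The fatty acid list (3 of 34 lower, likewise over the list alone, 0.0269) lost it without WT control replicates 1 or 5 or R502W mavacamten replicate 1 (-0.16 to -0.06), and the calcium handling (5 of 20 higher, 0.0485) and heat shock lists (3 of 21 higher, 0.0485) each in 8 of the 13 left-out runs, with medians from 0.11 to 0.23 and from 0.11 to 0.19. Erythroid markers (-0.38, 0.0424) lost their call in 6 runs, with medians from -0.53 to -0.25. The interferon list (0.96, 3 of 30 higher, camera adjusted p = 0.0101) stood at -0.12 without R502W mavacamten replicate 4. The cell cycle list (-0.87, camera adjusted p = 0.0178, no member passing) stood at -0.24 without WT control replicate 2, and also lost its call without R502W mavacamten replicates 3 or 4 (-0.85 and -0.90). With the length trend removed the calls of the calcium handling, matrix, fatty acid and erythroid lists ended as well (medians 0.04, 0.17, -0.06 and -0.18). All 7 lists had an adjusted p of 0.816 with an estimated correlation. The other 22 tested lists were not called; median and test differed in sign in the mitochondrially encoded, inflammation and mural lists.

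The rank correlation of fold change with exonic length was 0.36 here, and 542 of the 1232 calls remained with the length trend removed. The count ranged from 359 (without R502W mavacamten replicate 2) to 1213 over the left-out runs, with 462, 681 and 692 without R502W mavacamten replicates 3, 1 and 4, 688 without WT control replicate 3 and 716 without R502W control replicate 2; the share of calls that were higher was 72.2%, against 61.8% with RLE factors (668 and 413), 59.6% in DESeq2 (1073 and 727) and 60.8% with the length trend removed (394 and 254).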

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

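The test of the clock genes' direction, the length correction and the genotype score were chosen only after results had been seen; the other tests were planned. In each group of 4 or 5 libraries the list scores (mean log2 CPM) and the 12 fixed genes were searched for 1 library far from the rest of its group. These were 150 tests, of which chance picks about 1 in 20. The search found 10, close to that rate and all of them list scores, of which 4 were in WT control replicate 2.

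In WT control replicate 2 the calcium handling score was 7.21 against 7.47 to 7.54 in the other WT libraries (difference -0.29), the cell cycle score 3.52 against 0.81 to 1.55 (2.61), the ribosomal protein score 7.82 against 7.17 to 7.32 (0.60) and the skeletal muscle score 2.00 against 0.84 to 1.12 (0.94). In WT control replicate 1 the mitochondrially encoded score was 12.88 against 12.18 to 12.36 (0.63). In R502W control replicate 4 the extracellular matrix score was 5.13 against 5.41 to 5.45 (-0.29), and in R502W control replicate 3 the autophagy score was 7.01 against 6.92 (0.09). In R502W mavacamten replicate 4 the interferon score was 5.80 against 2.91 to 3.36 (2.51) and the autophagy score 6.85 against 6.94 to 6.95 (-0.09). In R502W mavacamten replicate 3 the oxidative stress score was 5.86 against 6.04 to 6.07 (-0.19).

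Long genes were higher and short genes lower in both R502W groups than in WT control. The median log2 deviation of expressed genes in the longest 20% minus that in the shortest 20% was -0.72 in WT control replicate 2. It ran from -0.23 to -0.05 in the other WT libraries and from 0.04 to 0.25 in the R502W libraries. With each library's length trend removed, 57.3% of the genotype calls stayed called in the same direction, which argues against the length trend as their whole cause. An effect of RNA quality or library preparation that does not follow exonic length would remain after this removal, so it was not tested. Among 55 markers of cells other than myocytes the rank correlation of fold change with length was 0.59 (permutation p = 1e-05, the smallest that 1e+05 resamples can give). That test shuffled genes measured in the same libraries, so it does not measure the spread between hearts. For these libraries the trend in the markers argues against a change in cardiomyocyte transcripts alone. RNA quality or library preparation may still account for the trend itself, and no batch is given in the labels.

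Clock genes stood apart between WT control and both R502W groups. Of the called clock genes 16 stayed called with the length trend removed, which argues against that trend as the cause. All 14 clock genes with a fixed phase moved in the direction set by Arntl, as hearts taken at another time of day could show. A clock changed by the genotype cannot be told apart from a different collection time, because each would separate the same groups.

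Genotype-changed genes lay on average nearer to WT under mavacamten, with no gene past edgeR's threshold (525 at an unadjusted p under 0.05; 6 by DESeq2, 2 by limma voom). With separate R502W controls in each comparison the lowest share of opposite signs over 6 splits was still 68%, which argues against the shared libraries as the only cause. Simulations with shared libraries and no drug effect reached 69.1%, but they are no reference for the splits, for which no simulation was run. Chance spread among the 8 R502W hearts may account for the shift, since the exact two-sided permutation p of the genotype score was 0.114 (0.0571 with the length trend removed). The choice of the score's genes disfavours genes that the drug returned to WT, so the score could miss such genes. A drug effect stays open.

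Other splits of the libraries were fitted in the same way. For R502W control against WT control, 1 of 100 splits (of 126 possible) gave as many genes as the real 1856. It was the real one, and the highest other gave 805. Chance alone is therefore unlikely, though 1 of 100 is the smallest share that these splits could give. For R502W mavacamten against WT control, which uses the same WT libraries, it was again 1 of 100. The real split gave 1232 genes against at most 154 in another, which differed only in placing WT control replicate 1 with the treated libraries. Chance alone is again unlikely. Such splits do not separate genotype from another difference between the same groups. For R502W mavacamten against R502W control the real count was 0 and the highest other split gave 0. All 35 of 35 splits must then give at least as many, so this count says nothing about chance.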

How the results depend on the processing

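The removal of the length trend, of 4 adipocyte-rich libraries and of mitochondrially encoded genes, and the adipocyte covariate, were chosen after the data were seen. For the results that moved, the cause was not tested, except that glmTreat asks for a larger change by construction.

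The count of 1856 genotype genes stayed within 1.5 times under RLE factors, library totals, DESeq2, voom, both filters, the fit of 2 groups, the atrial covariate, the length correction, the adipocyte covariate and the removal of mitochondrial genes (1246 to 2581). It was 456 with glmTreat, 963 with the sample number as a block, 545 with the Y covariate and 1145 without the 4 adipocyte-rich libraries, and 866 to 1870 with 1 library left out. The sample numbers were checked and do not pair the libraries.

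The treatment count of 0 by edgeR (525 genes at an unadjusted p under 0.05) was 6 with DESeq2 and 2 with voom, and 0 in each other alternative, including all 13 left-out runs.

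The count of 1232 genes in treated hearts against WT was 674 with library totals, 740 without a filter, 127 with glmTreat, 216 with only the 2 groups, 349 with the block, 629 with the atrial covariate, 74 with the Y covariate, 648 with the length trend removed and 653 without the adipocyte-rich libraries, and 359 to 1213 with 1 library left out. Under RLE factors, DESeq2, voom, the stricter filter, the adipocyte covariate and the removal of mitochondrial genes it was 1081 to 1800. Ddx3y, a member of the Y covariate, ran from 36.1 to 64.9 CPM in WT control libraries. It ran from 61.8 to 69.6 CPM in R502W control and from 62.4 to 73.8 CPM in treated libraries. That covariate may therefore take up part of the group difference in both comparisons with WT.

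The 80.4% of genotype-changed genes with the opposite sign under mavacamten became 88.4% with library totals, 76.9% with voom, 83.2% without a filter, 88.4% with glmTreat, 84.6% with the block, 85.8% with the atrial covariate, 90.8% with the Y covariate, 84.2% with the length trend removed, 88.1% at an adjusted p of 0.01 and 76.4% with split controls, and ran from 76.3 to 90.1% with 1 library left out.

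Of the list tests 47 were called, 0 with an estimated correlation and 9 with fry, and 41 to 50 with 1 library left out. The calls by fry were 7 in the genotype comparison, 0 in the treatment comparison and 2 in treated hearts against WT. DESeq2 and glmTreat gave no camera value. In treated hearts against WT, the interferon list's median was -0.12 without R502W mavacamten replicate 4, up to 1.244 over the left-out runs, and -0.02 without the adipocyte-rich libraries. The cell cycle list was 0.094 with the Y covariate and 0.097 without the adipocyte-rich libraries, Asph was -0.073 with the length trend removed, and Iigp1 was -0.033 without the adipocyte-rich libraries. No scaling moved the median of all genes by more than 0.049 in size (-0.049). At a median mean count of 237 per tested gene, spread between libraries and not depth set most SEs.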

Other observations

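The read shares below were examined after the data were seen. Mitochondrially encoded genes held 18.6 to 27.2% of the expected counts, and 24.1 to 35.9% together with their nuclear copies on chromosome 1 (24611535 to 24616197). Reads were divided differently between them in R502W control replicate 4 and R502W mavacamten replicate 1. There the copy Gm28661 was listed at 0 CPM, against 13573 to 29615 CPM in the other 11 libraries, and mt-Co3 stood at 23820 and 21219 CPM, against 4287 to 10840 CPM. Values of single mitochondrial genes are therefore not comparable between these libraries and the rest. Amd2, which shares reads with Amd1, stood at 14.2 ± 6.67 CPM in WT control, 8.92 ± 9.78 CPM in R502W control and 0.14 ± 0.10 CPM in R502W mavacamten.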
